A study of Mus musculus with 18 samples.

How the data were processed

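Gene expression was measured in P14 CD8 T cells, mouse T cells that carry a transgenic receptor for the GP33 peptide of lymphocytic choriomeningitis virus (LCMV). Per the labels, all samples came from female mice and spleen. Naive cells were taken directly from P14 mice, and effector cells were recovered from B6 mice that had received P14 cells and were infected with the Armstrong strain, on day 5 and on day 8. Total RNA and RNA bound by at least 3 ribosomes (polysome RNA) were prepared with Trizol, DNase and a column, amplified with the Ovation Pico WTA System V2 and labelled with biotin. The labels give neither the gate used to purify the cells nor whether replicates came from separate mice. Memory cells, which the protocol text also names, were not analysed here.

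The 18 arrays fall into 6 groups of 3, by 3 cell states and 2 kinds of RNA, and every array was used. The deposited values are one intensity per probe set for 45101 probe sets of a mouse whole-genome array. They are linear, and the authors had normalized them between arrays by a method that the labels do not state. The median intensity per array was between 84.8 and 92.4. Normalized values carry no absolute scale, so no statement about the total amount of RNA or of polysomes per cell is possible. For arrays there is no depth, and the number of arrays limits the precision. The median SE over genes was 0.17 for a log2 difference of 2 groups and 0.24 for a change of the ratio.

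Intensities were converted to log2(value + 16), which shrinks the differences of genes with low intensity. Of the probe sets, 34958 had 1 gene symbol in the reference annotation, 932 had several and 9211 were not listed. Probe sets were kept if their value lay above the array's median in at least 3 arrays. For each gene the probe set with the highest mean was used, which left 12390 of 18193 genes for testing. One linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom and a prior of 3.75 from empirical Bayes moderation. The 12 comparisons taken from it were polysome against total RNA in each state, the change of this ratio between states (the interaction of state and RNA type), and the states against each other in total RNA and in polysome RNA. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Values after ± are standard errors of the model (n = 3 arrays per group) unless SD is written. Pictures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

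Gene lists were fixed before the data were examined: cytosolic ribosomal proteins, other mRNAs with a terminal oligopyrimidine tract (TOP mRNAs), translation initiation factors, mTOR pathway and translation control, mitochondrial ribosomal proteins, ribosome biogenesis, cell cycle, cytotoxic effector genes, naive and memory-associated T cell genes, T cell receptor complex and inhibitory receptors, glycolysis, oxidative phosphorylation, proteasome, endoplasmic reticulum folding and unfolded protein response, type I interferon response, immediate-early genes, nuclear noncoding RNAs, small nucleolar RNA host genes, mitochondrially encoded mRNAs, and markers of B cells, myeloid cells, erythroid cells and platelets, and CD4 T cells and NK cells. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the 264 tests of 22 lists in 12 comparisons. None of the 13 mitochondrially encoded mRNAs had a tested probe set. Of the 264 tests, 110 were called at the preset correlation and 19 with an estimated correlation. The second count of a list's members, adjusted over the list alone, is given where it differs from the count over all genes. No called list had a median and a test of opposite sign.

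The named genes follow a rule fixed before the data were examined. For each polysome against total RNA comparison the 5 largest differences in each direction were taken, and for each change of the ratio and each total RNA comparison the 8 largest in each direction, among called genes whose arrays did not overlap between the groups (for a change of the ratio, whose 3 differences of equal-numbered arrays did not overlap). Provisional symbols were left out. Up to 4 members of each list with the smallest p were added, passed or not, and Gzmb, Ifng, Mki67, Myc, Eef1a1 and Rps6 are given in every comparison. Tcf7 and Rpl3 were to be given too but have no probe set with that symbol alone and were not analysed here. The text names only part of these genes, and leaves out most of those for which another probe set had the opposite sign.

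The model was tested on simulated data with 12390 genes and 3 arrays per group. Of these genes 50 were changed at each of the 4 fold sizes, and the rest had equal group means. Most real comparisons called far more genes, so their recovered shares may differ. Simulated total and polysome arrays of equal number shared part of their spread, a pairing that the labels do not state. The shared part cancels in the ratios, so the false shares of the ratio comparisons may be too low for unpaired arrays. For polysome against total RNA on day 8 it recovered 26%, 70%, 86% and 100% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold. For the change of the ratio between day 5 and day 8 it recovered 6%, 28%, 66% and 88%. For total RNA of day 5 against naive it recovered 20%, 66%, 84% and 100%, and for polysome RNA of day 8 against day 5 24%, 72%, 86% and 98%. Unchanged genes made up 2.1%, 2.1%, 4.3% and 7.9% of the calls in these 4 comparisons, the last above the 5% aimed for. Each share comes from a single draw with few false calls (3, 2, 6 and 12). With 3 arrays against 3, the smallest p that an exact two-sided permutation test can give is 0.1.

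Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, no filter, a filter on the mean over all arrays, the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, a variance trend with robust moderation, array weights, fitting only the groups compared, a minimum change of 2-fold, a pseudocount of 1, the array number as a replicate block, the covariance of polysome on total values, an estimated correlation in the list tests, and leaving out each array in turn. Leaving out both arrays of a replicate number that stood apart and adding probe sets of several symbols were chosen after seeing the data.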

Results

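Total and polysome-associated RNA of virus-specific CD8 T cells was profiled on 18 arrays. P14 T cells were analysed as naive cells and as effector cells 5 and 8 days after LCMV infection, with 3 arrays of total RNA and 3 of polysome RNA per state. Polysome RNA is RNA bound by 3 or more ribosomes. Its ratio to total RNA reports how much of a transcript is engaged by several ribosomes, relative to the other transcripts of the same cells. The first principal component over genes held 48.0% of the variance and set naive cells apart from day 5 cells, with day 8 cells between them. The second, with 22.0%, set day 8 apart from both. The third, with 15.8%, set polysome apart from total RNA. Arrays of 1 group had correlations across genes from 0.960 to 0.996. Naive cells came from P14 mice and effector cells from infected B6 hosts, so host and infection differ together. Replicates may be technical repeats, in which case the p-values measure only the spread between the samples that were made. The difference of the Gapdh control probes at the 3' and 5' end, a sign of RNA integrity and priming, was 1.59, 0.74 and 1.24 in total RNA of naive, day 5 and day 8 cells and 0.90, 0.44 and 0.71 in polysome RNA (mean log2, n = 3 each). For Actb it was -0.11, -0.10 and -0.04 in total and -0.12, -0.15 and -0.10 in polysome RNA. For 18S rRNA it was 0.54, 0.52 and 0.49 in total and 0.48, 0.45 and 0.41 in polysome RNA.

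Which transcripts are held on or off polysomes was asked first in naive cells. Several noncoding transcripts lay far below their total RNA level on polysomes. Neat1, the scaffold RNA of nuclear paraspeckles, differed by -4.18 ± 0.32 on the log2 scale, the long noncoding RNA Dancr by -3.43 ± 0.38 and the nuclear RNA Malat1 by -1.99 ± 0.17. All 11 of 11 tested small nucleolar RNA host genes, whose introns hold small nucleolar RNAs, were lower on polysomes (median -2.12, camera adjusted p = 2.2e-14, or adjusted p = 0.0061 with an estimated correlation). Snhg6 stood at -2.45 ± 0.16 and Snhg12 at -2.42 ± 0.16. Of 8 nuclear noncoding RNAs, 5 were lower (median -0.93, adjusted p = 4.9e-05, or adjusted p = 0.023 with an estimated correlation). Some transcripts of ribosomal proteins were also below total RNA. Of 43 tested, 14 were lower and none was higher (median -0.20, adjusted p = 1.2e-07, or adjusted p = 0.072 with an estimated correlation). Rps6, a protein of the small subunit, differed by -1.76 ± 0.14, Rpl12 by -2.87 ± 0.23 and Rpl14 by -1.39 ± 0.15. Other TOP mRNAs, which share their 5' motif and its control by mTOR, had 6 of 22 members lower (1 higher and 6 lower adjusted over the list alone) (median -0.11, adjusted p = 0.013, or adjusted p = 0.24 with an estimated correlation). Pabpc1, the poly(A)-binding protein, was among them with -0.73 ± 0.14.

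In the same naive cells 17 of 36 proteasome subunits were above total RNA on polysomes and none was below (19 higher and 0 lower adjusted over the list alone) (median 0.37, adjusted p = 1.7e-06, or adjusted p = 0.093 with an estimated correlation). Psmb2 stood at 0.85 ± 0.11 and Psma7 at 0.69 ± 0.11. Glycolysis genes had 7 of 19 members higher (9 higher and 1 lower adjusted over the list alone) (median 0.35, adjusted p = 0.033, or adjusted p = 0.42 with an estimated correlation). The triosephosphate isomerase Tpi1 was one of them with 0.75 ± 0.13. Nuclear-encoded oxidative phosphorylation genes were mixed, with 9 higher and 19 lower of 72 (9 higher and 22 lower adjusted over the list alone) (median -0.10, adjusted p = 0.027, or adjusted p = 0.81 with an estimated correlation). They ran from the succinate dehydrogenase subunit Sdhc with 1.11 ± 0.12 to the small cytochrome oxidase subunit Cox7c with -2.22 ± 0.20. The largest higher values belonged to Spsb1, a SOCS box protein, with 1.97 ± 0.19, the conjugating enzyme Ube2l6 with 1.79 ± 0.29 and Dvl2, a Wnt signal transducer, with 1.74 ± 0.15. The stress transcription factor Ddit3 was lower with -1.63 ± 0.12 and the chemokine Ccl5 with -1.77 ± 0.21. Mki67, a proliferation marker, was lower too (-0.80 ± 0.13, adjusted p = 0.00031). The cytotoxic protease Gzmb (0.42 ± 0.17, adjusted p = 0.076), Myc (0.33 ± 0.20, adjusted p = 0.23), Ifng (-0.04 ± 0.15, adjusted p = 0.87) and the elongation factor Eef1a1 (0.00 ± 0.08, adjusted p = 0.97) did not pass. In limma 3212 of 12390 genes passed, 1678 higher and 1534 lower on polysomes. Of these 684 differed at least 2-fold. Over all 12390 genes, called or not, the 3 arrays of one kind of RNA lay entirely on one side of the other 3 in 5323 (43.0%), where chance gives 10%. Without naive total replicate 1 the count was 2401. Fitted on the naive arrays alone it was 2057, and with array weights 5394. Replicate 3 stood apart, with weights of 0.24 in total and 0.21 in polysome RNA, against 1.2 to 2.4 in the other naive arrays.

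On day 5 noncoding RNAs were again far below their total RNA level on polysomes. Neat1 differed by -3.55 ± 0.32 and Dancr by -2.95 ± 0.38. The 11 small nucleolar RNA host genes were all lower (median -1.87, adjusted p = 2.1e-12, or adjusted p = 0.011 with an estimated correlation), as Snhg5 with -2.29 ± 0.16. Nuclear noncoding RNAs had 4 of 8 lower and 1 higher (median -0.60, adjusted p = 0.0026, or adjusted p = 0.072 with an estimated correlation). Of 43 ribosomal protein mRNAs 11 were lower (0 higher and 8 lower adjusted over the list alone), with a median of -0.06 (adjusted p = 0.036, or adjusted p = 0.49 with an estimated correlation). Rps6 differed by -0.39 ± 0.14, adjusted p = 0.040. TOP mRNAs had 3 higher and 2 lower of 22 (median 0.05, adjusted p = 0.99). Of 36 proteasome subunits 19 were higher (21 higher and 0 lower adjusted over the list alone) (median 0.36, adjusted p = 1.7e-05, or adjusted p = 0.13 with an estimated correlation). Psmc5 stood at 0.60 ± 0.12. Cox7c had the largest lower value of the named genes with -3.76 ± 0.20. Among oxidative phosphorylation genes 9 were higher and 22 lower (median -0.14, adjusted p = 0.027, or adjusted p = 0.81 with an estimated correlation). Among regulators of translation, Rptor of mTOR complex 1 was higher with 1.70 ± 0.42 and Rictor of mTOR complex 2 lower with -1.42 ± 0.27. Their list of 39 genes was not called (median 0.17, adjusted p = 0.94).

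Mki67 (-0.94 ± 0.13, adjusted p = 0.00010) and Ifng (-0.44 ± 0.15, adjusted p = 0.033) were lower on polysomes on day 5. Myc (0.42 ± 0.20, adjusted p = 0.10), Gzmb (0.03 ± 0.17, adjusted p = 0.89) and Eef1a1 (-0.01 ± 0.08, adjusted p = 0.91) did not pass. In limma 4662 genes passed, 2707 higher and 1955 lower, 732 of them by at least 2-fold. Over all tested genes the arrays did not overlap in 5939 (47.9%), against 10% by chance. Without both day 5 arrays of replicate 2, whose polysome array stood apart from the rest, 2177 genes passed. Fitted on the day 5 arrays alone 2394 did.

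On day 8 most ribosomal protein mRNAs lay below their total RNA level on polysomes. Of 43 ribosomal protein mRNAs 32 were lower on polysomes and none was higher (0 higher and 34 lower adjusted over the list alone), with a median of -0.54 (adjusted p = 1.0e-15, or adjusted p = 0.011 with an estimated correlation). Rps6 differed by -2.07 ± 0.14, Rpl12 by -2.22 ± 0.23, Rpl14 by -1.82 ± 0.15 and Rps26 by -1.29 ± 0.11, all in 3 of 3 arrays. Of 22 other TOP mRNAs 13 were lower and none was higher (median -0.31, adjusted p = 5.3e-05, or adjusted p = 0.072 with an estimated correlation). Among them were Pabpc1 with -1.26 ± 0.14, the elongation factor subunit Eef1b2 with -0.96 ± 0.09, the initiation factor subunit Eif3f with -0.94 ± 0.09 and Eef1a1 with -0.37 ± 0.08, adjusted p = 0.0023. Mitochondrial ribosomal proteins had 9 higher and 27 lower of 74 (9 higher and 29 lower adjusted over the list alone) (median -0.21, adjusted p = 0.0081, or adjusted p = 0.76 with an estimated correlation). For oxidative phosphorylation 10 were higher and 30 lower (10 higher and 31 lower adjusted over the list alone) (median -0.25, adjusted p = 0.00044, or adjusted p = 0.59 with an estimated correlation). The small nucleolar RNA host genes were all lower once more (median -2.03, adjusted p = 1.3e-11, or adjusted p = 0.011 with an estimated correlation). Of the nuclear noncoding RNAs 5 were lower and 1 higher (median -0.96, adjusted p = 0.0011, or adjusted p = 0.061 with an estimated correlation).

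Higher on polysomes on day 8 were 17 of 36 proteasome subunits, as Psmd12 with 0.74 ± 0.11 (median 0.35, adjusted p = 0.00022, or adjusted p = 0.18 with an estimated correlation). Glycolysis genes had 9 of 19 higher and 1 lower (10 higher and 1 lower adjusted over the list alone) (median 0.35, adjusted p = 0.036, or adjusted p = 0.42 with an estimated correlation). The lactate transporter Slc16a3 stood at 1.25 ± 0.21 and the pyruvate kinase Pkm at 0.54 ± 0.10. The helicase Eif4a1, an initiation factor, was higher with 1.32 ± 0.12 and Eif2a was lower with -1.28 ± 0.15. Of 28 initiation factors 10 were higher and 5 lower (median 0.20, adjusted p = 0.38). The largest higher values were those of Hsd17b12, a fatty acid elongation enzyme, with 1.85 ± 0.22, the purine synthesis enzyme Atic with 1.83 ± 0.16 and the tryptophanyl-tRNA synthetase Wars with 1.82 ± 0.14. Ifng, the main antiviral cytokine of these cells, was lower on polysomes (-1.22 ± 0.15, adjusted p = 1.8e-05), as was Mki67 (-0.70 ± 0.13, adjusted p = 0.00053). Myc was higher (0.77 ± 0.20, adjusted p = 0.0060) and Gzmb did not pass (0.16 ± 0.17, adjusted p = 0.48). In limma 5208 genes passed, 2845 higher and 2363 lower, 1165 of them by at least 2-fold. Arrays did not overlap in 8112 (65.5%) of all tested genes, against 10% by chance. Without both day 8 arrays of replicate 1, which held the highest levels of myeloid and B cell markers, 2811 genes passed.

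Across the 3 states 817 genes were higher and 913 lower on polysomes in every state, where independent lists would give 84.2 and 46.2. The states share no arrays, but their tests share each gene's estimate of spread, which by itself raises the overlap. A further 23 genes were called in opposite directions in 2 states. Across genes, which are not independent replicates, the ratio of naive cells correlated with that of day 5 at r = 0.71, day 5 with day 8 at r = 0.79 and naive with day 8 at r = 0.81 (Spearman's rho 0.67, 0.76 and 0.78, 3 relations).

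**Figure D1:**
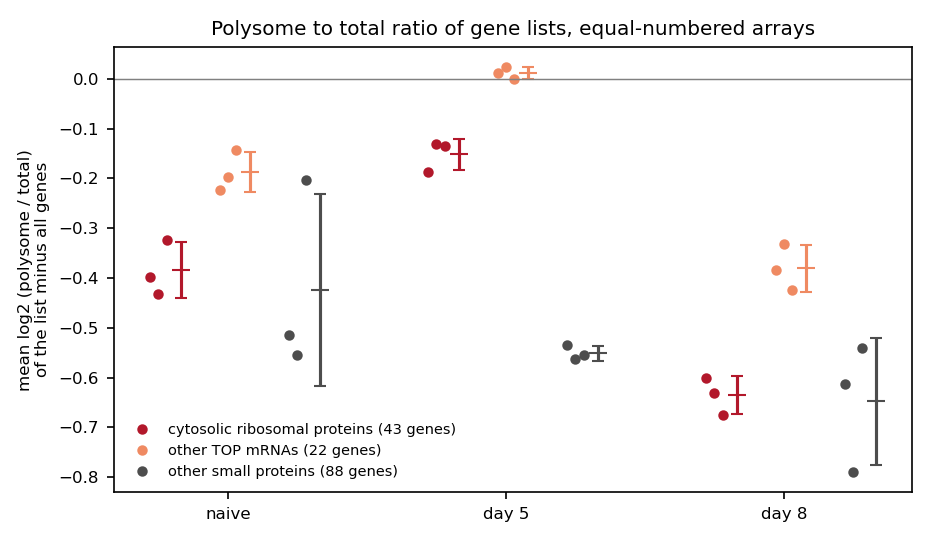
Polysome to total ratio of 3 gene lists, as mean log2 ratio of the list minus that of all genes. Points are the differences of the 3 pairs of equal-numbered arrays of naive, day 5 and day 8 cells, which need not share a preparation, and bars the mean ± SD. Ribosomal protein mRNAs lie at -0.38 ± 0.06 in naive cells, -0.15 ± 0.03 on day 5 and -0.64 ± 0.04 on day 8.

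Whether the ratio itself changed from naive cells to day 5 was tested as the interaction of state and kind of RNA. The ratio of some ribosomal protein mRNAs rose: Rps6 by 1.37 ± 0.20, adjusted p = 0.0037 and Rpl14 by 1.45 ± 0.21, adjusted p = 0.0036. The list as a whole had a median of 0.19, with 2 of 43 members up and none down (adjusted p = 0.00035, or adjusted p = 0.20 with an estimated correlation). The other TOP mRNAs had a median of 0.18 (adjusted p = 0.0079, or adjusted p = 0.20 with an estimated correlation). None of them was called over all genes, and 4 were up adjusted over the list alone. Ratios that fell included that of Mir155hg, the host transcript of a microRNA (-2.20 ± 0.30, adjusted p = 0.0031). Those of the mitotic motor Kif15 (-1.98 ± 0.29) and the kinetochore protein Kntc1 (-2.12 ± 0.31) fell too. Cox7c fell (-1.54 ± 0.28, adjusted p = 0.018), the cytokine receptor chain Il2rb (-0.69 ± 0.15, adjusted p = 0.041) and the kinetochore protein Cenpf (-0.84 ± 0.19, adjusted p = 0.048). Cenpf was the 1 called of 55 cell cycle genes (median -0.13, adjusted p = 0.013, or adjusted p = 0.33 with an estimated correlation). The stress factor Ddit3 rose by 1.10 ± 0.18, adjusted p = 0.0064. Gzmb (-0.38 ± 0.24, adjusted p = 0.47), Ifng (-0.40 ± 0.21, adjusted p = 0.41), Mki67 (-0.13 ± 0.18, adjusted p = 0.78), Myc (0.10 ± 0.28, adjusted p = 0.91) and Eef1a1 (-0.02 ± 0.12, adjusted p = 0.96) did not pass.

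In limma 130 of 12390 genes changed their ratio from naive to day 5, 51 up and 79 down. For 108 of these total RNA had changed as well. With each array centred on its median the split was 43 up and 111 down. The count rests on single arrays: it was 83 without naive total replicate 1, 81 without naive total replicate 3, 51 without day 5 total replicate 1, and 79 without day 5 total replicate 2. It was 81 without naive polysome replicate 2, 232 without day 5 polysome replicate 3 and 67 without both day 5 arrays of replicate 2. On the 4 groups alone it was 24 and with array weights 868. It was 78 with polysome values adjusted for total RNA by covariance, which turned the sign of Mir155hg, Cox7c, Il2rb, Cenpf and the cell cycle list.

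From day 5 to day 8 the polysome to total ratio of ribosomal protein mRNAs fell. Of 43 tested, 12 fell and none rose (27 fell adjusted over the list alone). The median was -0.45 (adjusted p = 1.4e-23, or adjusted p = 0.0027 with an estimated correlation). Rps6 fell (-1.67 ± 0.20, adjusted p = 0.0016), Rpl14 (-1.88 ± 0.21, adjusted p = 0.0016), Rps26 (-0.95 ± 0.15, adjusted p = 0.010) and Rps7 (-0.85 ± 0.13, adjusted p = 0.0084). Other TOP mRNAs fell too, 4 of 22 over all genes and 9 adjusted over the list alone, with a median of -0.32 (adjusted p = 6.5e-10, or adjusted p = 0.011 with an estimated correlation). Eef1b2 fell (-0.98 ± 0.13, adjusted p = 0.0037), Eif3f (-0.92 ± 0.13) and Eif3h (-0.64 ± 0.13). Over the same interval total RNA of ribosomal proteins had a median change of -0.01, with 3 of 43 lower (adjusted p = 0.69). In polysome RNA 29 fell (0 higher and 33 lower adjusted over the list alone) with a median of -0.50 (adjusted p = 1.1e-08, or adjusted p = 0.061 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.30 with 2 of 74 down (0 higher and 5 lower adjusted over the list alone) (adjusted p = 6.2e-06, or adjusted p = 0.47 with an estimated correlation). Mrpl45 was one of them with -0.89 ± 0.20. Other measures of the same arrays were mixed. The Gapdh 3' to 5' difference was 0.74 on day 5 and 1.24 on day 8 in total RNA, while that of Actb was -0.10 and -0.04 and that of 18S rRNA 0.52 and 0.49. The mean level of the macrophage gene Lyz2 was 7.34 and 12.5.

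Initiation factors went both ways between day 5 and day 8. Eif5b rose by 0.84 ± 0.18, adjusted p = 0.039, and Eif2a fell (-0.97 ± 0.21, adjusted p = 0.039) and Eif3m (-1.04 ± 0.19, adjusted p = 0.019). Their list was not called (adjusted p = 0.93). The chemokine Ccl5 rose by 1.31 ± 0.29, adjusted p = 0.046, the noncoding RNA Miat fell (-2.37 ± 0.45, adjusted p = 0.020) and Ddit3 fell (-1.08 ± 0.18, adjusted p = 0.010). Cell cycle genes had a median of 0.25 with no member called (adjusted p = 6.4e-05, or adjusted p = 0.13 with an estimated correlation). Small nucleolar RNA host genes had one of -0.24 with 1 of 11 down (0 higher and 2 lower adjusted over the list alone) (adjusted p = 0.0087, or adjusted p = 0.27 with an estimated correlation). Ifng (-0.78 ± 0.21, adjusted p = 0.11), Eef1a1 (-0.35 ± 0.12, adjusted p = 0.18), Gzmb (0.12 ± 0.24, adjusted p = 0.89), Mki67 (0.24 ± 0.18, adjusted p = 0.64) and Myc (0.35 ± 0.28, adjusted p = 0.67) did not pass. In limma 121 genes changed their ratio, 49 up and 72 down. For 55 of them the change was at least 2-fold. The count was 39 and 54 without day 5 total replicates 1 and 2, and 65, 47 and 37 without day 8 total replicates 1, 2 and 3. It was 74 and 68 without day 8 polysome replicates 1 and 2, 32 without both day 5 arrays of replicate 2, and 7 without both day 8 arrays of replicate 1. It was 1050 with array weights and 74 with covariance, which turned the sign of Rpl14 and of the cell cycle list. The ribosomal protein median stayed between -0.48 and -0.45 when arrays were left out.

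The ratio of day 8 cells was then compared with that of naive cells. Ifng was lower on polysomes relative to total RNA on day 8 (-1.18 ± 0.21, adjusted p = 0.028). Its level was above naive by 6.17 in total and 4.99 in polysome RNA. The naive ratio, measured at so much lower a level, may be compressed by the array background. The change of the Ifng ratio from day 5 to day 8 did not pass. Mir155hg fell (-2.00 ± 0.30, adjusted p = 0.012), and the noncoding RNAs Miat (-2.24 ± 0.45) and Morrbid (-1.51 ± 0.28) fell. Ccl5 rose by 1.47 ± 0.29, adjusted p = 0.045 and the neuropeptide receptor component Ramp1 by 1.45 ± 0.24, adjusted p = 0.022. The ribosomal protein list had a median of -0.29 with no member called over all genes and 12 lower adjusted over the list alone (adjusted p = 2.9e-13, or adjusted p = 0.020 with an estimated correlation). Other TOP mRNAs had one of -0.24 with 4 lower adjusted over the list alone (adjusted p = 9.7e-05, or adjusted p = 0.079 with an estimated correlation). Oxidative phosphorylation genes (-0.15, adjusted p = 0.0070, or adjusted p = 0.74 with an estimated correlation), mitochondrial ribosomal proteins (-0.28, adjusted p = 1.9e-06, or adjusted p = 0.44 with an estimated correlation) and small nucleolar RNA host genes (-0.28, adjusted p = 0.027, or adjusted p = 0.36 with an estimated correlation) had lower medians without a called member. Rps6 (-0.31 ± 0.20, adjusted p = 0.62), Eef1a1 (-0.37 ± 0.12, adjusted p = 0.21), Gzmb (-0.26 ± 0.24, adjusted p = 0.74), Mki67 (0.11 ± 0.18, adjusted p = 0.88) and Myc (0.44 ± 0.28, adjusted p = 0.60) did not pass.

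In limma 42 ratios differed between naive and day 8, 11 up and 31 down. With arrays centred on their medians 9 were up and 51 down. The count was 12, 9 and 17 without naive total replicates 1, 2 and 3, and 7, 11 and 9 without day 8 total replicates 1, 2 and 3. It was 27 and 3 without naive polysome replicates 1 and 2, 10 and 24 without day 8 polysome replicates 1 and 2, and 3 without both day 8 arrays of replicate 1. It was 524 with array weights, 20 with a pseudocount of 1 and 1 with covariance, under which Ifng, Ramp1, Morrbid and Mir155hg turned sign.

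Total RNA of day 5 against naive cells answers what the first days of the response change in transcript levels. Gzmb rose by 6.71 ± 0.17 on the log2 scale, a 105-fold increase, Ifng by 5.49 ± 0.15 and the protease Gzma by 4.13 ± 0.12. Of 44 cytotoxic effector genes 32 rose and 3 fell (median 2.57, adjusted p = 5.0e-15, or adjusted p = 0.040 with an estimated correlation). All 55 of 55 cell cycle genes rose, with a median of 4.21 (adjusted p = 3.9e-40, or adjusted p = 0.00040 with an estimated correlation). Kif2c, a mitotic kinesin, rose by 6.35 ± 0.31, the thymidine kinase Tk1 by 5.57 ± 0.13 and Mki67 by 4.68 ± 0.13. Naive and memory-associated genes fell, 27 of 33 with 1 rising (median -1.74, adjusted p = 8.5e-12, or adjusted p = 0.057 with an estimated correlation). Dapl1 stood at -5.85 ± 0.27 and Treml2 at -4.48 ± 0.17. Of the inhibitory receptors named here, Havcr2 rose by 5.77 ± 0.14, Pdcd1 by 4.95 ± 0.20 and Ctla4 by 3.80 ± 0.20. The list that holds them went both ways, 10 up and 10 down of 27 (11 higher and 10 lower adjusted over the list alone) (median -0.06, adjusted p = 0.43). Among the largest losses were Il6ra, an interleukin-6 receptor chain, with -5.52 ± 0.40 and the integrin Itgae with -5.94 ± 0.29.

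Many members of metabolic and protein quality lists also rose on day 5, while none of the lists in this paragraph was called with an estimated correlation. Glycolysis genes had 13 of 19 up and 1 down (median 0.96, adjusted p = 8.0e-05, or adjusted p = 0.13 with an estimated correlation). The hexokinase Hk2 rose by 3.55 ± 0.14. Mitochondrial ribosomal proteins had 48 of 74 up and 1 down (52 higher and 1 lower adjusted over the list alone) (median 0.66, adjusted p = 8.8e-09, or adjusted p = 0.33 with an estimated correlation). Oxidative phosphorylation genes had 27 of 72 up (24 higher and 0 lower adjusted over the list alone) (median 0.32, adjusted p = 0.0017, or adjusted p = 0.65 with an estimated correlation). Proteasome subunits had 27 of 36 up (29 higher and 1 lower adjusted over the list alone) (median 0.60, adjusted p = 2.9e-06, or adjusted p = 0.098 with an estimated correlation). Endoplasmic reticulum folding and unfolded protein response genes had 21 of 32 up and 3 down (median 0.63, adjusted p = 6.1e-05, or adjusted p = 0.075 with an estimated correlation). Of the stress response members, the asparagine synthetase Asns rose by 4.89 ± 0.22 and Ddit3 stood at -2.03 ± 0.12. Initiation factors had 14 of 28 up, as the cap-binding Eif4e with 1.00 ± 0.11 (median 0.38, adjusted p = 0.0045, or adjusted p = 0.091 with an estimated correlation). Ribosome biogenesis genes had 18 of 47 up (17 higher and 0 lower adjusted over the list alone), as Bysl with 0.89 ± 0.18 (median 0.30, adjusted p = 0.019, or adjusted p = 0.59 with an estimated correlation). Ribosomal proteins themselves had a median of -0.10 with 1 up and 4 down (0 higher and 0 lower adjusted over the list alone) (adjusted p = 0.21). TOP mRNAs had one of -0.07 (adjusted p = 0.73) and the mTOR pathway one of 0.00 with 7 up and 13 down (adjusted p = 0.46).

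Type I interferon response genes were lower on day 5 than in naive cells, 18 of 28 with none higher (1 higher and 19 lower adjusted over the list alone) (median -0.90, adjusted p = 1.7e-05, or adjusted p = 0.28 with an estimated correlation). Ifit3 stood at -4.12 ± 0.16. Immediate-early genes had 16 of 25 lower and 3 higher (median -0.83, adjusted p = 0.00096, or adjusted p = 0.16 with an estimated correlation). Egr1 stood at -2.24 ± 0.17 and Cd69 at -2.59 ± 0.17. Myc was lower (-0.75 ± 0.20, adjusted p = 0.0048), while Eef1a1 (-0.05 ± 0.08, adjusted p = 0.66) and Rps6 (-0.24 ± 0.14, adjusted p = 0.19) did not pass. Markers of other cells gave no called list. Myeloid markers had a median of 0.09 with 5 of 21 up (adjusted p = 0.14), and B cell markers -0.57 with 1 up and 3 down of 11 (adjusted p = 0.47). Erythroid and platelet markers had -0.10 with none of 4 called (adjusted p = 0.87). CD4 T cell and NK cell markers had -0.22 with 1 up and 2 down of 5 (adjusted p = 0.93). In limma 5949 genes changed, 2896 up and 3053 down, 2764 by at least 2-fold. In 7268 (58.7%) of all tested genes the arrays did not overlap, against 10% by chance.

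**Figure D2:**
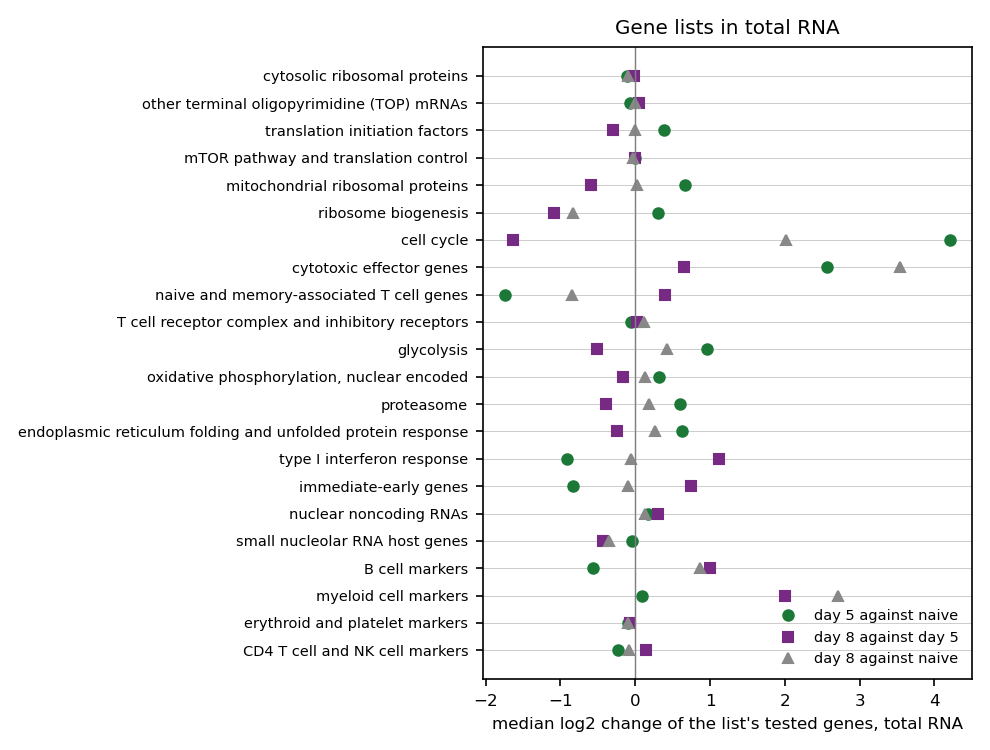
Median log2 change in total RNA of 22 gene lists in 3 comparisons of cell states, each point 1 list, with 3 arrays per group. Cell cycle genes lie at 4.21 for day 5 against naive and at -1.63 for day 8 against day 5.

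From day 5 to day 8 cell cycle and ribosome biogenesis genes fell in total RNA, and a majority of cytotoxic effector genes rose. Of 55 cell cycle genes 54 fell and none rose (median -1.63, adjusted p = 4.9e-28, or adjusted p = 0.00090 with an estimated correlation). The mitotic kinase Plk1 fell (-2.87 ± 0.14), Tk1 (-2.56 ± 0.13) and Mki67 (-0.67 ± 0.13, adjusted p = 0.00044). Ribosome biogenesis genes fell, 40 of 47 with none rising (0 higher and 41 lower adjusted over the list alone) (median -1.09, adjusted p = 7.7e-16, or adjusted p = 0.057 with an estimated correlation). Nop2 stood at -1.77 ± 0.12 and Grwd1 at -2.39 ± 0.16, and Myc fell (-1.57 ± 0.20, adjusted p = 9.4e-06). Cytotoxic effector genes rose, 26 of 44 with 3 falling (median 0.65, adjusted p = 9.8e-07, or adjusted p = 0.16 with an estimated correlation). The chemokine receptors Cx3cr1 and Ccr2 rose by 3.86 ± 0.29 and 3.51 ± 0.22 and the transcription factor Zeb2 by 3.28 ± 0.21. Myeloid markers were higher in the same day 8 arrays, as Lyz2 by 5.13 ± 0.80. The interleukin-2 receptor chain Il2ra fell (-2.25 ± 0.18). Il7r, the interleukin-7 receptor, rose by 3.66 ± 0.33. Of 33 naive and memory-associated genes 13 rose and 3 fell (median 0.40, adjusted p = 0.013, or adjusted p = 0.47 with an estimated correlation). The largest fall was that of Bcat1, which starts the breakdown of branched-chain amino acids, with -4.82 ± 0.18, followed by the neurofilament Nefh with -4.63 ± 0.54 and the chemokine Xcl1 with -4.52 ± 0.28.

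Interferon response genes were higher on day 8 than on day 5, 19 of 28, as Ifit3 with 3.48 ± 0.16 (median 1.12, adjusted p = 1.3e-06, or adjusted p = 0.22 with an estimated correlation). Immediate-early genes had 16 of 25 higher and 1 lower (16 higher and 2 lower adjusted over the list alone) (median 0.75, adjusted p = 0.00061, or adjusted p = 0.16 with an estimated correlation). Ier3 was one of them with 2.51 ± 0.24. Mitochondrial ribosomal proteins fell, 45 of 74 with 2 rising (2 higher and 50 lower adjusted over the list alone) (median -0.59, adjusted p = 1.5e-09, or adjusted p = 0.31 with an estimated correlation). So did 12 of 19 glycolysis genes with 3 rising (median -0.51, adjusted p = 0.013, or adjusted p = 0.33 with an estimated correlation). Initiation factors fell in 12 of 28 with 2 rising (2 higher and 13 lower adjusted over the list alone) (median -0.30, adjusted p = 0.0013, or adjusted p = 0.065 with an estimated correlation). For proteasome subunits 24 fell and 2 rose (2 higher and 25 lower adjusted over the list alone) (median -0.38, adjusted p = 0.00036, or adjusted p = 0.19 with an estimated correlation). For oxidative phosphorylation 17 fell and 1 rose (1 higher and 13 lower adjusted over the list alone) (median -0.17, adjusted p = 0.030, or adjusted p = 0.81 with an estimated correlation). The amino acid transporter Slc7a5 fell (-2.52 ± 0.13) and the mTOR inhibitor Sesn1 rose by 2.29 ± 0.32. Their mTOR list was not called (median 0.00, adjusted p = 0.99). Endoplasmic reticulum folding and unfolded protein response genes had 4 up and 15 down (median -0.24, adjusted p = 0.030, or adjusted p = 0.32 with an estimated correlation). Small nucleolar RNA host genes had 4 of 11 down (median -0.43, adjusted p = 0.031, or adjusted p = 0.37 with an estimated correlation). The receptor list had 11 up and 6 down (median 0.03, adjusted p = 0.73). Other TOP mRNAs had a median of 0.05 (adjusted p = 0.82).

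Markers of other spleen cells were higher on day 8. Of 21 myeloid markers 15 were higher than on day 5 and none was lower (median 2.00, adjusted p = 6.7e-05, or adjusted p = 0.42 with an estimated correlation). Of 11 B cell markers 7 were higher and 1 lower (8 higher and 1 lower adjusted over the list alone) (median 1.01, adjusted p = 0.043, or adjusted p = 0.63 with an estimated correlation). The macrophage lysozyme Lyz2 was higher by 5.13 ± 0.80 and the receptor Csf1r by 4.45 ± 0.84, with arrays of day 8 far apart. Lyz2 stood at 13.9, 13.1 and 10.4 in day 8 total RNA replicates 1, 2 and 3, against 6.9 to 8.1 on day 5. The integrin Itgax, also a marker of dendritic cells, stood between 12.85 and 12.88 in the 3 arrays of day 8. Gains of the cytotoxic, interferon and immediate-early lists were measured in the same day 8 arrays. Ifng rose by 0.68 ± 0.15, adjusted p = 0.0016. Gzmb (-0.23 ± 0.17, adjusted p = 0.30), Eef1a1 (0.06 ± 0.08, adjusted p = 0.61) and Rps6 (-0.29 ± 0.14, adjusted p = 0.12) did not pass. In limma 5304 genes changed, 2859 up and 2445 down, 2134 by at least 2-fold. Arrays did not overlap in 8140 (65.7%) of all tested genes, against 10% by chance.

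**Figure D3:**
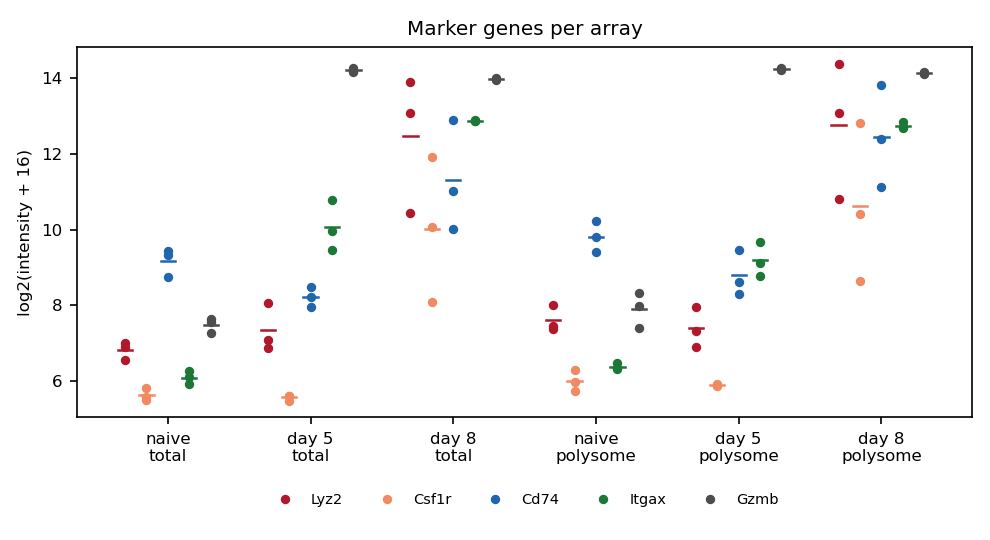
Level of Lyz2, Csf1r, Cd74, Itgax and Gzmb as log2(intensity + 16) on each of the 18 arrays, by cell state and kind of RNA, with a bar at each group's mean. Lyz2 differs between the day 8 arrays (13.9, 13.1 and 10.4 in total RNA) more than Itgax does (12.85 to 12.88).

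Total RNA of day 8 cells against naive cells gives the state at the later time. Of 44 cytotoxic genes 39 rose and 1 fell (39 higher and 2 lower adjusted over the list alone) (median 3.54, adjusted p = 2.8e-35, or adjusted p = 0.0027 with an estimated correlation). Gzmb was up by 6.49 ± 0.17, Ifng by 6.17 ± 0.15, Zeb2 by 6.34 ± 0.21 and the natural killer receptor Klrc1 by 6.29 ± 0.21. Cell cycle genes were still above naive, 49 of 55 (49 higher and 1 lower adjusted over the list alone) with a median of 2.01 (adjusted p = 1.0e-31, or adjusted p = 0.00060 with an estimated correlation). Mki67 was up 16-fold. Naive and memory-associated genes were below it, 21 of 33 with 2 above (2 higher and 22 lower adjusted over the list alone) (median -0.84, adjusted p = 2.9e-10, or adjusted p = 0.070 with an estimated correlation). The lymph node homing receptor Ccr7 fell (-5.32 ± 0.32). Ribosome biogenesis genes were below naive, 31 of 47 with none above (median -0.83, adjusted p = 8.3e-12, or adjusted p = 0.089 with an estimated correlation). Myc was below it as well (-2.32 ± 0.20, adjusted p = 1.1e-07). Ribosomal proteins had 7 of 43 lower (0 higher and 4 lower adjusted over the list alone) (median -0.10, adjusted p = 0.020, or adjusted p = 0.42 with an estimated correlation). Rps6 was among them (-0.52 ± 0.14, adjusted p = 0.0096), and Eef1a1 did not pass (0.01 ± 0.08, adjusted p = 0.97).

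Glycolysis genes were above naive on day 8, 11 of 19 with 2 below (12 higher and 2 lower adjusted over the list alone) (median 0.43, adjusted p = 0.0027, or adjusted p = 0.24 with an estimated correlation). So were 13 of 32 endoplasmic reticulum folding and unfolded protein response genes (13 higher and 1 lower adjusted over the list alone) (median 0.27, adjusted p = 0.0012, or adjusted p = 0.15 with an estimated correlation) and 8 of 36 proteasome subunits (6 higher and 0 lower adjusted over the list alone) (median 0.18, adjusted p = 0.022, or adjusted p = 0.42 with an estimated correlation). The receptor list had 8 of 27 above and 2 below (median 0.12, adjusted p = 0.013, or adjusted p = 0.24 with an estimated correlation). Havcr2 rose by 5.50 ± 0.14 and Lag3 by 2.44 ± 0.17. Interferon response genes had a median of -0.05 with 3 up and 7 down (adjusted p = 0.61). Myeloid markers were above naive in 17 of 21 (median 2.72, adjusted p = 1.7e-08, or adjusted p = 0.23 with an estimated correlation), with Itgax up by 6.78 ± 0.25. B cell markers went both ways, 6 up and 2 down (median 0.86, adjusted p = 0.21). In limma 4027 genes differed, 2155 up and 1872 down, 1633 by at least 2-fold. With array weights the count was 7252. Arrays did not overlap in 7082 (57.2%) of all tested genes, against 10% by chance.

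Polysome RNA changed much as total RNA did. From naive to day 5 all 55 of 55 cell cycle genes rose (median 4.17, adjusted p = 3.8e-36, or adjusted p = 0.00040 with an estimated correlation). Of 44 cytotoxic genes 34 rose and 3 fell (34 higher and 4 lower adjusted over the list alone) (median 2.23, adjusted p = 6.8e-13, or adjusted p = 0.057 with an estimated correlation). Gzmb rose by 6.33 ± 0.17, Ifng by 5.09 ± 0.15, Mki67 by 4.54 ± 0.13 and Rps6 by 1.13 ± 0.14, adjusted p = 5.8e-06. Myc fell (-0.65 ± 0.20, adjusted p = 0.011) and Eef1a1 did not pass (-0.07 ± 0.08, adjusted p = 0.50). From day 5 to day 8 cell cycle genes fell, 54 of 55 (median -1.42, adjusted p = 1.7e-21, or adjusted p = 0.0023 with an estimated correlation). Mki67 fell (-0.43 ± 0.13, adjusted p = 0.010), Myc (-1.22 ± 0.20, adjusted p = 9.5e-05), Rps6 (-1.96 ± 0.14, adjusted p = 3.7e-08) and Eef1a1 (-0.30 ± 0.08, adjusted p = 0.0069). Ifng (-0.10 ± 0.15, adjusted p = 0.63) and Gzmb (-0.10 ± 0.17, adjusted p = 0.64) did not pass. Mitochondrial ribosomal proteins had 59 of 74 down (0 higher and 62 lower adjusted over the list alone) (median -0.87, adjusted p = 4.6e-15, or adjusted p = 0.18 with an estimated correlation). Other TOP mRNAs had 15 of 22 down and 1 up (median -0.34, adjusted p = 0.0025, or adjusted p = 0.16 with an estimated correlation). In the same day 8 polysome arrays the myeloid marker Lyz2 stood at 14.4, 13.1 and 10.8, against 6.9 to 8.0 on day 5. Against naive cells, day 8 polysome RNA held more Gzmb (6.22 ± 0.17), Ifng (4.99 ± 0.15) and Mki67 (4.11 ± 0.13) and less Myc (-1.87 ± 0.20), Rps6 (-0.83 ± 0.14) and Eef1a1 (-0.37 ± 0.08). Of 43 ribosomal proteins 31 were lower (0 higher and 32 lower adjusted over the list alone) (median -0.43, adjusted p = 1.7e-11, or adjusted p = 0.032 with an estimated correlation).

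In limma 6386 genes changed in polysome RNA from naive to day 5 (3193 up, 3193 down), 5679 from day 5 to day 8 (2872 up, 2807 down) and 3759 from naive to day 8 (1788 up, 1971 down). Of these 2926, 2342 and 1580 changed at least 2-fold. Of all tested genes, arrays did not overlap in 6489 (52.4%), 6217 (50.2%) and 5229 (42.2%), against 10% by chance. Both kinds of RNA were called in the same direction for 4764, 4032 and 2710 genes and in opposite directions for 17, 19 and 5. Across all genes, which are not independent replicates, the change on polysomes correlated with that in total RNA at r = 0.93, 0.89 and 0.92 (Spearman's rho 0.86, 0.85 and 0.76) in the 3 comparisons.

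**Figure D4:**
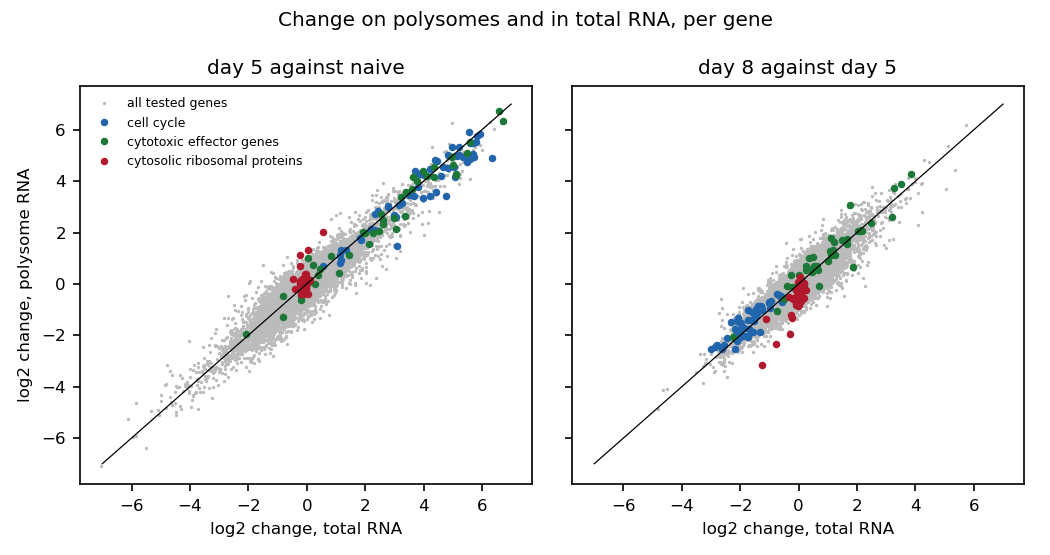
Log2 change on polysomes against log2 change in total RNA of every tested gene, for day 5 against naive and day 8 against day 5, with cell cycle, cytotoxic and ribosomal protein genes coloured and a black line of equal change. Ribosomal protein genes lie below the line for day 8 against day 5, with a median of -0.50 on polysomes and -0.01 in total RNA.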

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

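The results below are differences between cell states in the polysome to total ratio, each called by the test of the difference itself, and a pattern of marker genes in total RNA. Of the tests, those of short mRNAs, of myeloid RNA, of other TOP mRNAs and all 3 of the marker genes were chosen only after the result was seen. The test of brightness and the splits of the arrays were chosen before.

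The number of genes whose ratio changed was 130 from naive to day 5, 121 from day 5 to day 8 and 42 from naive to day 8. The median change of the ribosomal protein list was 0.19, -0.45 and -0.29 in these comparisons and that of other TOP mRNAs 0.18, -0.32 and -0.24. Mitochondrial ribosomal proteins had -0.30 from day 5 to day 8 and -0.28 from naive to day 8. Cell cycle genes had -0.13 from naive to day 5 and 0.25 from day 5 to day 8. Oxidative phosphorylation genes had -0.15 from naive to day 8. Small nucleolar RNA host genes had -0.24 from day 5 to day 8 and -0.28 from naive to day 8. Of these 13 list results, 3 were also called with an estimated correlation: ribosomal proteins from day 5 to day 8 (adjusted p = 0.0027) and from naive to day 8 (adjusted p = 0.020), and other TOP mRNAs from day 5 to day 8 (adjusted p = 0.011).

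A total of 17 genes were called above total RNA on polysomes in one state and below it in another, with a called change of the ratio between states. From naive to day 5 the ratio changed by 1.09 for Adam6b, 1.06 for E130215H24Rik, 1.05 for Trmu, 0.61 for Nop53, -0.97 for Smc2, -1.29 for Pigm, -1.45 for Atp23 and -1.60 for Xxylt1. From day 5 to day 8 it changed by 1.10 for Parp4, 1.09 for Taok1, 0.89 for Copa, 0.86 for Cblb, 0.84 for Eif5b, 0.80 for Myh9, 0.77 for Arid1a and -0.61 for Cct5, and from naive to day 8 by -1.01 for Tspan13. Each gene is given here in the comparison with its lowest adjusted p, and some were called in a second. Trmu (-1.04), Nop53 (-0.62) and Pigm (0.94) turned back from day 5 to day 8. Cblb (-0.81), Copa (-0.71), Myh9 (-0.64) and Tspan13 (-0.74) had fallen from naive to day 5. From naive to day 8 Adam6b (1.11) and Atp23 (-1.54) were called too.

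The pattern most worth following is the lower ratio of ribosomal protein mRNAs on day 8 than on day 5, -0.45 in the median. Compression of the brightest probe sets is argued against, since 0% of 10000 random lists matched in brightness had a median as low (the lowest was -0.04 and the highest 0.22). A loss of short mRNAs from the fraction with 3 or more ribosomes is argued against as the whole cause of this fall. The 88 mRNAs of other small proteins had a median of -0.14 (95% bootstrap interval over genes -0.22 to -0.03). These genes vary together, so the interval does not measure the spread between arrays. Their list mean over pairs of equal-numbered arrays was -0.55 on day 5 (SD 0.015) and -0.65 on day 8 (SD 0.13). That of ribosomal proteins was -0.15 (SD 0.03) and -0.64 (SD 0.04). From naive to day 8 the small proteins had a median of -0.25, near the -0.29 of ribosomal proteins. That comparison therefore gives no such argument. RNA of cells that carry Lyz2 is argued against too. Without both day 8 arrays of replicate 1, which have the highest marker levels, the median was -0.48. In proportion to Lyz2, -0.27 would remain (59.4% of its mean intensity left, SE 0.03 over pairs of equal-numbered arrays). A candidate explanation that stays open is lower ribosome loading of mRNAs with a 5' terminal oligopyrimidine tract. Of 10000 matched lists, 0% had a median as low as the other TOP mRNAs (lowest -0.12). That restates a fall already seen and is no separate support. The unstated normalization and RNA integrity stay open beside this candidate. The 3' to 5' differences in total RNA of day 5 and day 8 were 0.74 and 1.24 for Gapdh. They were -0.10 and -0.04 for Actb and 0.52 and 0.49 for 18S. RNA of cells without Lyz2, B cells and cells outside the marker lists among them, was not tested and stays open too.

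The other pattern is the higher level of marker genes of other spleen cells on day 8 than on day 5. Of the markers, 15 of 21 myeloid and 7 of 11 B cell genes were called higher, and Cd22 was lower by 1.48. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 among the B cell markers are class II genes that myeloid and dendritic cells express too. The other B cell markers called higher were Cd79a (1.01), Cd79b (0.62) and Ms4a1 (0.98). Cd79a stood at 8.42, 7.24 and 7.49 in day 8 total replicates 1, 2 and 3, against 7.20 to 7.38 in naive cells. Only replicate 1 was far above naive. Ms4a1 stood at 7.32, 6.05 and 6.68, against 5.71 to 5.96. Cells that carry Lyz2 are argued against as the source of the higher Itgax. In day 8 total replicates 1 and 3 Lyz2 stood at 13.9 and 10.4 while Itgax stood at 12.85 and 12.88. In day 8 replicates 2 and 3 Itgax lay 1.57 above its level in proportion to Lyz2 (mean log2 of 4 arrays, SD within groups 0.34). In total and polysome RNA this excess was 0.69 and 0.99 in replicate 2, and 2.13 and 2.48 in replicate 3, so it was far smaller in replicate 2. The class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had SDs of 1.46, 1.41, 1.59 and 1.47 over the day 8 total RNA arrays, against 0.0156 for Itgax. This argues against the cells whose class II level varied as the source of the steady Itgax. In total RNA Itgax stood at 5.92 to 6.25 in naive cells and at 9.45 to 10.78 on day 5. Cd74 stood at 8.74 to 9.43 and then at 7.94 to 8.50. Whether Itgax came from the T cells, from other cells or from dendritic cells of equal share in each replicate stays open. For the other markers, RNA of other spleen cells and expression by the effector T cells are not fully told apart here. The counts only restate the pattern. The SD over day 8 total RNA arrays was under 0.263, the 95th percentile of all genes, in 3 of the 15 myeloid markers. These were Itgax (0.0156), Cst3 (0.145) and Cd68 (0.246), where the median gene had 0.085 and Lyz2 1.81. Looked at after the pattern was seen, the list means of myeloid and B cell markers had SDs of 0.91 and 0.86 over these arrays. That of cytotoxic effector genes had 0.011. This argues against a steady level in the effector T cells as the source of the markers that varied. A level in T cells that differed between replicates is not excluded, and the labels give no gate used for purification. In day 8 total RNA the 4 highest means of myeloid markers were those of Itgax (12.87), Lyz2 (12.5), Cst3 (12.25) and Lyz1 (12.14) and the 2 highest of B cell markers those of Ighm (12.11) and Cd74 (11.3), on probes that are not comparable between genes.

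Other splits of the same arrays into groups of equal size were counted for each comparison, and 10 splits are too few for a share under 0.05. Every other split also mixes arrays of the groups compared, so real differences enter the spread and low counts follow. The low counts below therefore decide nothing. For the ratio in naive, day 5 and day 8 cells the real split gave 3212, 4662 and 5208 genes and the highest other split 2, 5 and 48. For the 3 changes of the ratio it gave 130, 121 and 42 against 0 in every other split. For total RNA it gave 5949, 5304 and 4027 against 0. For polysome RNA it gave 6386, 5679 and 3759 against 10, 1 and 0.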

How the results depend on the processing

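The alternatives were chosen before the data were examined, except leaving out both arrays of a replicate number and adding probe sets of several symbols, which were chosen after seeing the data. Of 638 called results for named genes, 469 kept their direction and their side of the threshold in every setting but the minimum change of 2-fold, and of 110 called list results 19 did. Genes near the array background show compressed differences, because log2(value + 16) and the background of the probes set a floor. The correlation of changes on polysomes with those in total RNA stayed between 0.916 and 0.939, between 0.876 and 0.899 and between 0.904 and 0.920 when arrays were left out.

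With array weights 5394 genes were called for the ratio in naive cells, 868, 1050 and 524 for the changes of the ratio (naive to day 5, day 5 to day 8, naive to day 8) and 7252 for total RNA of day 8 against naive. With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, 2057 and 2394 were called for the ratio in naive and day 5 cells and 24 for the change from naive to day 5. A minimum change of 2-fold left 684, 732 and 1165 for the ratios, 55 for the change from day 5 to day 8, 2764, 2134 and 1633 for total RNA and 2926, 2342 and 1580 for polysome RNA, by its construction. With a pseudocount of 1 the change from naive to day 8 had 20 genes. For array weights and the pseudocount the cause was not tested. Total and polysome arrays of equal number had residuals correlated over 0.1 in 8 of 9 pairs, and 8 of 9 correlated best with their own number. But 5 of 18 pairs across states, which cannot share a preparation, were over 0.1 too. All of these were pairs of naive with day 5 arrays (0.10 to 0.33), and no pair with a day 8 array was. The labels state no pairing, so the main model has no replicate block. With it, 276 and 294 genes were called for the changes of the ratio from naive to day 5 and from day 5 to day 8, more than doubling these counts.

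With the covariance of polysome on total values 78, 74 and 1 genes were called for the 3 changes of the ratio. Its slope is estimated from deviations within groups of 9 pairs, so large changes in total RNA may be poorly corrected, which was not tested. Under it the signs turned from naive to day 5 for Metap1d (-0.24), Ramp1 (-1.74), Il2rb (0.64), Cenpf (5.29), Cox7c (0.61), Fam81a (2.87), Eldr (1.31), Mir1949 (2.05), Mir155hg (0.84) and the cell cycle list (1.59), from day 5 to day 8 for Mir1949 (-2.02), Fam81a (-2.47), Crebl2 (0.97), Use1 (0.000382), Rpl14 (0.43) and the cell cycle list (-0.76), and from naive to day 8 for Ramp1 (-1.45), Adam6b (-0.70), Rdh5 (-0.033), Ifng (1.17), Morrbid (0.88), Mir22hg (2.44) and Mir155hg (1.06). The ribosomal protein list (0.13) and other TOP mRNAs (0.17) then missed the threshold from naive to day 5. With an estimated correlation between genes 19 list tests were called, and the medians 0.19 of ribosomal proteins and 0.18 and -0.24 of other TOP mRNAs (naive to day 5, and naive to day 8) missed it, since members of a list vary together.

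With the mean of all probe sets the ratio turned for Id2 (-0.056 in naive, -0.25 in day 5 and -0.30 in day 8 cells), Hif1a (-0.13 in naive and -0.024 in day 8 cells), Egr3 (-0.031 and -0.27 in the same), Itgal (0.018) and Ighm (0.035) on day 5, as did the change of Btg1 from naive to day 5 (0.023) and Ighm in total RNA of day 8 against naive (0.74), since their probe sets differ in sign. Without probe sets ending in _x_at or _s_at Dkc1 turned (0.60 in naive and 1.00 in day 8 cells), and without a filter the change of Pla2g4c from naive to day 5 (0.017), in both because another probe set stands for the gene.

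Leaving out arrays gave 2401 to 2963 genes for the ratio in naive cells, 2177 to 5065 on day 5 and 2811 to 4618 on day 8 (3253 and 3903 at the lowest without a single array), 51 to 232, 7 to 149 and 3 to 36 for the changes of the ratio, 5219 to 5601, 4417 to 4854 and 3142 to 3544 for total RNA, and 5665 to 6615, 4999 to 5803 and 3066 to 3403 for polysome RNA. The lowest of 7 and of 3 were reached without both day 8 arrays of replicate 1, that of 3 also without naive polysome replicate 2 alone. The ribosomal protein median stayed between 0.15 and 0.19, between -0.48 and -0.45 and between -0.33 and -0.24 for the 3 changes of the ratio, and that of other TOP mRNAs between 0.10 and 0.22, between -0.35 and -0.30 and between -0.25 and -0.17. With probe sets of several symbols 71 ribosomal protein genes had medians of 0.14, -0.47 and -0.33, and 23 other TOP mRNAs 0.20, -0.34 and -0.26.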

Other observations

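The gene lists in this part were chosen after seeing the data, with p-values adjusted over the 60 tests of these lists. Enzymes of one-carbon metabolism and purine synthesis, which feed nucleotide production, rose from naive to day 5 in total RNA in 19 of 21 genes (median 0.93, adjusted p = 5.9e-07, or adjusted p = 0.034 with an estimated correlation) and fell from day 5 to day 8 in 19 (median -1.61, adjusted p = 2.0e-12, or adjusted p = 0.0064 with an estimated correlation). Psat1 of serine synthesis changed by 2.26 ± 0.15 and -1.76 ± 0.15 in these comparisons, Mthfd2 of the mitochondrial folate cycle by 1.80 ± 0.16 and -1.37 ± 0.16 and Shmt2 by 0.81 ± 0.14 and -2.09 ± 0.14. Against naive cells 13 were lower on day 8 and 3 higher (median -0.57, adjusted p = 0.0040, or adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis genes had 9 of 19 higher on day 5 than in naive cells (median 0.36, adjusted p = 0.012, or adjusted p = 0.21 with an estimated correlation) and 11 lower on day 8 than on day 5 with 1 higher (median -0.51, adjusted p = 0.0023, or adjusted p = 0.17 with an estimated correlation), with the squalene epoxidase Sqle at 1.46 ± 0.15 and -1.22 ± 0.15.

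Receptors for chemokines, sphingosine phosphate and homing changed in both directions between day 5 and day 8, 16 of 24 up and 5 down (median 0.58, adjusted p = 0.0014, or adjusted p = 0.17 with an estimated correlation). S1pr5, which directs exit from tissues, rose by 3.99 ± 0.24 and Cxcr6 by 1.85 ± 0.14, while the gut-homing receptor Ccr9 changed by -2.63 ± 0.19 and Cxcr4 by -1.58 ± 0.19. Myeloid cells express several of these receptors, and 15 of 21 myeloid markers were higher in the same day 8 arrays (Lyz2 by 5.13). Host transcripts of microRNAs and other long noncoding RNAs lay below total RNA on polysomes in every state: 7 of 12 in naive cells (median -0.70, adjusted p = 5.7e-05, or adjusted p = 0.0064 with an estimated correlation), 10 on day 5 (median -2.00, adjusted p = 5.3e-10, or adjusted p = 0.00096 with an estimated correlation) and 10 on day 8 (median -1.86, adjusted p = 2.0e-08, or adjusted p = 0.0012 with an estimated correlation). Their ratio was lower on day 5 than in naive cells (median -0.38, 4 called, 0 higher and 5 lower adjusted over the list alone, adjusted p = 7.1e-05, or adjusted p = 0.0064 with an estimated correlation), but the list includes genes already known to be called and is no independent evidence. Xist, the noncoding RNA of the inactive X chromosome in these cells of female mice, stood at 9.70, 11.78 and 9.46 in total RNA of naive, day 5 and day 8 cells, a change of 2.09 ± 0.17 and then of -2.33 ± 0.17. The list of 88 mRNAs of small proteins, not called with an estimated correlation, had polysome to total medians of -0.42, -0.54 and -0.72 in naive, day 5 and day 8 cells and 37, 52 and 58 members lower and 3, 2 and 3 higher (45, 53 and 62 lower and 5, 2 and 6 higher adjusted over the list alone) (adjusted p = 0.24, 0.17 and 0.17 with an estimated correlation).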
